A study of Caenorhabditis elegans with 12 samples.

How the data were processed

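The series measured H4K5ac and H4K8ac by ChIP-seq in mid-L4 N2 worms kept for 12 h at 25 °C on P. aeruginosa PA01. IP and input libraries were made for each mark, with 3 replicates per group and 12 libraries in all. Groups and replicate numbers came from the labels. Per the labels' protocols, libraries were prepared with a NEBNext Ultra DNA kit from fragments of 0.2 to 1 kb and sequenced as single-end reads. The submitters' processing notes name bcl2fastq 2.17, Trimmomatic 0.33, Bowtie 1.1.2 and MACS2 2.1.0, without settings or order. They name WBcel235, and the chromosome accessions in the deposited files are those of that build. A human build is named there as well, and its role is not given in the sources used here.

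The deposited files hold estimated counts of reads that need not be whole, not scaled for depth, and the sources used here do not say over which window they were counted. They are unscaled because totals differ between libraries. Of the values, 71.1% (H4K5ac) and 72.7% (H4K8ac) were multiples of 1 over 12 within 0.005, where 12% would be by chance, as when a read is divided among overlapping features. Input levels did not grow in step with gene length: over 5 equal groups of protein-coding genes by length, the median input was 166 to 208 CPM (counts scaled to the library total) in H4K5ac, while the median length went from 969 to 10501 bases. The 6 files of a mark list the same regions, with 10 other columns identical, so regions were called once per mark. Each region carries a gene, and values are per gene: 539 H4K5ac genes and 409 H4K8ac genes have more than 1 region and a single value. Region names run up to 7920 (H4K5ac) and 7379 (H4K8ac), above the 6101 and 5409 regions listed, so the lists may already be a selection. Reads outside the listed genes are not counted here, so total depth is unknown. Regions start on a grid of 200 bases and are 599 to 65599 bases wide in H4K5ac (quartiles 1999 and 7599) and 599 to 78799 in H4K8ac (quartiles 2399 and 8799), 36.0 and 38.0 Mb in sum. Neighbouring or overlapping genes can share a region and reads, as with bath-36 and Y75B12B.16 or R03E9.7 and R03E9.10, so their values are not independent.

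Gene names altered to dates by spreadsheet software (7 in H4K5ac, 4 in H4K8ac) were recovered from the annotated transcript where the reference held it (7 and 3). Of the listed genes, 5393 (99.7%) and 4858 (99.6%) were found in the RefSeq gene table of WBcel235, which has 19983 protein-coding genes among 46926. Of the names in the gene lists, 7 were not found there.

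Counts were rounded to whole numbers for edgeR 4.0.16 (R 4.3.3, limma 3.58.1). IP and input were compared within each mark, and the marks were compared over the 6 IP libraries for genes with values in both. Libraries were scaled by TMM, the quasi-likelihood test was used, p-values were adjusted by the Benjamini-Hochberg method over all genes of a comparison, and the threshold was an adjusted p of 0.05. TMM sets the typical listed gene near 0. All listed genes had been selected as carrying the mark, so a gene below 0 has less signal than the typical listed gene and need not lack the mark. No filter was applied, the lowest count of any gene in any library being 31.7. Levels are CPM over the TMM-scaled total of the listed genes (between marks, the shared genes) ± SD over 3 libraries. Log2 ratios have the standard error of the fit. The design had foreseen regions, but the files hold values per gene, so genes were tested. In simulated data with 200 genes changed, the H4K5ac test recovered 98% of 1.5-fold and 4% of 1.2-fold changes, with 14 and 3 false calls. That of H4K8ac recovered 100% and 71% (22 and 15), and that between marks 100% and 38% (3 and 5). False calls exceeded 5% of calls in each mark.

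The gene lists, the rule for named genes, the tests of genes, the list tests within each mark and a set of alternative settings were fixed before the data were examined. The rank test of lists was applied to the difference between marks after the data were seen. The 25 lists were immune regulators of the p38 MAPK and related pathways, pathogen response effectors, C-type lectins, lysozymes and saposin-like proteins, UDP-glucuronosyltransferases with glutathione transferases and cytochrome P450s, autophagy and lysosome, mitochondrial stress, ER stress, heat shock, insulin signalling and oxidative stress, histone acetyltransferases and deacetylases, core histones, ribosomal proteins, translation and cytoskeleton genes used in all cells, collagens, markers of intestine, muscle, neurons, germline and hypodermis, chemoreceptors, nuclear hormone receptors, F-box, BATH and MATH genes, major sperm proteins and pals genes. Some genes stand on more than 1 list. Presence among a mark's genes was tested by Fisher's exact test (two-sided) against all protein-coding genes. The median ratio of the listed members was tested against 100000 random lists of protein-coding listed genes (two-sided permutation test, at least 5 members, smallest possible p = 2e-05). Both were adjusted by Benjamini-Hochberg over the lists, and the second was repeated under each setting. These tests treat genes as independent, which neighbours are not. In simulated data 2.5% of unchanged lists fell below 0.05, and 80% of lists of 30 genes shifted by 0.3 were recovered. The rule named, per mark, the 10 genes with the highest IP level and the 10 largest rises and 10 largest falls with 1 direction in every replicate pair. It also named up to 4 members of each list by IP level, the 10 largest differences between marks in each direction, and 8 genes whatever their values (mys-1, trr-1, pmk-1, tir-1, sek-1, hlh-30, irg-1 and lys-7). Overlap of regions was taken with bedtools 2.31.1 at a minimum of 1 base, and shares have Wilson intervals of 95%. Exact permutation tests over libraries cannot go below 0.1 with 3 against 3.

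Same-numbered H4K5ac IP and input libraries deviated together from their group means (r across genes = 0.60, 0.27 and 0.55 for replicates 1, 2 and 3, each above the limit of 0.1), so by that limit the numbers pair them. Values are from the fit without the block, as fixed beforehand. Blocked values are given where a named gene's call changed, not for every list count that moved. Of the unmatched pairs, IP replicate 3 with input replicate 2 (0.44) and IP replicate 2 with input replicate 3 (0.14) also lay above it, so input replicate 2 correlated best with another number. Deviations from a group mean cancel each other, and input replicate 1 stood apart (-0.54 with IP replicate 3). The values of the 3 numbers are therefore not independent and do not show 3 separate pairings. With the number as a block, 4173 genes passed in place of 3456. No library was a plain copy of another. The closest pairs were H4K8ac inputs 2 and 3 and H4K5ac inputs 2 and 3, with a chi-square of 1.17 and 1.26 per degree of freedom. Counting error alone would give a value near 1, so these values do not show that the inputs are independent samples. Inputs of different marks could be nearly as close, with 1.72 for H4K5ac input 3 and H4K8ac input 1.

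Settings chosen then as alternatives were DESeq2 1.42.0 with its size factors, a filter at the lower quartile (25%) of counts, the replicate block, leaving out each library, genes of promoter regions only (promoter class or within 1000 bases of a start), genes with a ratio above the median of the list, another background for the lists, and overlap of at least 50% of both regions. Chosen after the data were seen were scaling to the lowest 5% of genes, leaving out a replicate number in both groups of IP against input, DESeq2 between marks, taking marks relative to their inputs (interaction term, with and without H4K5ac input replicate 1), and removal of a trend of the difference on H4K8ac enrichment (lowess, span 0.3). Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9 was used for the other steps. GC content was not examined, as no genome sequence was used here.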

Results

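Wild-type C. elegans of the N2 strain were grown at 20 °C on the laboratory food strain E. coli OP50, moved as mid-L4 larvae to lawns of the bacterial pathogen P. aeruginosa PA01, and collected after 12 h at 25 °C. Chromatin sheared to fragments of 0.2 to 1 kb was immunoprecipitated (IP) with an antibody to histone H4 acetylated at lysine 5 (H4K5ac) or at lysine 8 (H4K8ac), and IP and input DNA were sequenced. Acetylation of these lysines in the H4 tail is a mark found at active genes. The 12 libraries formed 4 groups of 3, namely H4K5ac IP, H4K5ac input, H4K8ac IP and H4K8ac input. Counts over the listed genes summed to 8286326, 11309502 and 11263009 in the H4K5ac IP libraries, 8325581, 7546369 and 6303691 in their inputs. They summed to 9058004, 7595638 and 7520759 in the H4K8ac IP libraries and 6857897, 6625914 and 6837389 in theirs. All libraries came from exposed worms, so an effect of the exposure itself was not tested. The labels do not say that replicates came from separate cultures, so p-values measure only the spread between these samples, which may be technical.

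The purpose the study states is to find genes that H4 acetylation could regulate in worms on the pathogen. The deposited lists held 6101 H4K5ac regions taken to 5409 genes and 5409 H4K8ac regions taken to 4876 genes, 1 list per mark for all 6 libraries, so shares of regions have no spread between replicates. In the deposited annotation 39.8% of H4K5ac regions (95% Wilson interval 38.5 to 41) and 38.9% of H4K8ac regions (37.6 to 40.2) lay at promoters, intervals that cover counting error only. Introns held 20.5% and 20.8% of regions, exons 16.3% and 14.5%, transcript ends 13.5% and 14.8%, and intergenic sequence 9.97% and 10.9%, for H4K5ac and H4K8ac in that order. Regions were broad, with a median width of 3999 bases for H4K5ac and 4599 bases for H4K8ac. Chromosome X carried 19.7% of the H4K5ac regions and 17.1% of the H4K8ac regions. Of the listed genes, 73.5% (H4K5ac) and 75.2% (H4K8ac) were protein-coding.

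H4K5ac, IP against input. The chaperone genes hsp-60 and hsp-1 were among the 10 largest ratios of IP over input in H4K5ac. The largest ratio was at R107.5 (chromosome III, 9043201 to 9065199, build WBcel235, region at the promoter), with 901 ± 66.2 CPM in the IP and 219.8 ± 14.9 CPM in the input (SD, n = 3 each), a log2 ratio of 2.04 ± 0.13 (SE, adjusted p = 2.05e-06, edgeR quasi-likelihood test with Benjamini-Hochberg adjustment). Next were hsp-60, the mitochondrial chaperonin, at 1.93 ± 0.14 (chromosome III, 1612801 to 1625999, promoter), bath-36, a BATH-domain gene, at 1.90 ± 0.10 (chromosome V, 15183001 to 15194599, transcript end), and hsp-1, a cytosolic Hsp70 chaperone, at 1.82 ± 0.11 (chromosome IV, 17265801 to 17292799, promoter). The non-coding genes linc-90 (1.87 ± 0.14), F16A11.9 (1.82 ± 0.13), W06H8.14 (1.80 ± 0.10), M04B2.10 (1.78 ± 0.13) and R03E9.7 (1.74 ± 0.12) and the protein-coding gene mstr-1 (1.78 ± 0.11) completed the 10 largest ratios. Among the 10 genes with the highest IP level stood also F53C11.5 (1.72 ± 0.13), the proteasome subunit gene pbs-1 (1.57 ± 0.16), a non-coding gene at chromosome IV, 16488001 to 16507599 (1.69 ± 0.16), dlk-1 (1.53 ± 0.14), a kinase of axon regeneration, M01H9.6 (1.51 ± 0.14) and Y39G10AR.11 (1.32 ± 0.13).

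The ratios are relative to the typical listed gene, because the scaling sets that gene near 0. On this scale 1719 of 5409 genes were higher in IP than in input and 1737 were lower, whereas scaling to the lowest 5% of genes, which moved every ratio up by 0.50, gave 3837 higher and 0 lower (edgeR, and 0 lower at an unadjusted p under 0.05). The 10 lowest genes lay between -0.54 and -0.53, a far narrower reach than at the top. They were the protein-coding genes frm-5.1 (-0.54 ± 0.10), C04E6.7 (-0.54 ± 0.12), C15C8.7 (-0.53 ± 0.09), C02F4.4 (-0.53 ± 0.12), C44H9.5 (-0.53 ± 0.12) and sphr-1 (-0.53 ± 0.12), the piRNA gene 21ur-10726 (-0.54 ± 0.11) and the non-coding genes C14F5.8 (-0.53 ± 0.09), F10E9.17 (-0.53 ± 0.12) and C16B8.5 (-0.53 ± 0.09). For frm-5.1, which encodes a FERM-domain protein, levels were 119.5 ± 3.97 CPM in the IP and 174 ± 23.6 CPM in the input (SD, n = 3 each, adjusted p = 9.2e-04, edgeR). Without replicate 3 in both groups the count of 3456 genes past the threshold became 2213. Input replicate 1 stood apart from input replicates 2 and 3, and without it 3718 genes passed.

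Among lists fixed beforehand, ribosomal protein genes and translation and cytoskeleton genes lay above the typical listed gene in H4K5ac (values are log2 IP over input ± SE, n = 3 libraries a side). Ribosomal protein genes had 9 of 78 members listed, 9 higher and 0 lower, with a median of 0.97 (adjusted permutation p = 0.00132 over lists), among them rpl-14 (0.87 ± 0.08), rpl-21 (0.97 ± 0.08), rps-11 (0.88 ± 0.09) and rpl-11.1 (1.01 ± 0.12). Of 9 listed translation and cytoskeleton genes used in all cells 8 were higher (median 0.94, adjusted permutation p = 0.00147), including the tubulins tba-1 (1.47 ± 0.11) and tba-2 (1.63 ± 0.12), the actin act-4 (1.00 ± 0.10) and iscu-1 (0.94 ± 0.11), an iron-sulphur cluster gene on that list. Autophagy and lysosome genes had 11 higher and 1 lower of 15 (median 0.46, adjusted permutation p = 0.0505), led by epg-9 (1.11 ± 0.11), atg-3 (1.28 ± 0.09), epg-7 (0.80 ± 0.09) and the lysosomal membrane gene lmp-1 (0.62 ± 0.08). Genes of the ER stress response had 6 higher and 1 lower of 11 (median 0.50, adjusted permutation p = 0.0609). The BiP chaperone gene hsp-4 (0.90 ± 0.11), the kinase gene pek-1 (0.91 ± 0.10), the disulphide isomerase gene pdi-3 (1.42 ± 0.08) and the calreticulin gene crt-1 (1.31 ± 0.09) were higher. The mitochondrial stress list had 4 listed members, too few for its rank test, of which hsp-60, the transcription factor genes atfs-1 (0.56 ± 0.09) and dve-1 (0.72 ± 0.09) were higher and spg-7 (0.03 ± 0.08) did not pass (median 0.64). Of 5 listed heat shock genes, 3 were higher, with hsp-1 and hsp-16.2 (0.24 ± 0.08) among them, hsp-17 (-0.21 ± 0.13) did not pass, and hsf-1, the heat shock transcription factor, was lower (-0.28 ± 0.09, 0.22 when scaled to the lowest 5%), with a median of 0.24 (adjusted permutation p = 0.489). With 1 library left out, the rank tests of the autophagy list (IP 2, input 2 or input 3, adjusted permutation p = 0.0364, 0.0255 and 0.0283) and of the ER stress list (IP 1, input 2 or input 3, 0.024, 0.0379 and 0.0426) passed. Heat shock genes then had 2 higher and 0 lower without input 3, and a median of 0.16 without IP 3. The 1 lower ER stress gene no longer passed without IP 1, input 2 or input 3. Leaving out 1 library ended the call of hsp-16.2 (IP 2 or 3 or input 2 or 3, 0.16 to 0.26) and hsf-1 (input 3, -0.35 to -0.22), where the library and the range of the log2 ratio over all 6 omissions are given. Gained calls were those of hsp-17 (input 1, -0.34 to -0.09). With replicate numbers as a block, hsp-17 (-0.22) passed, as did the autophagy list (adjusted permutation p = 0.0489), and 2 ER stress genes were lower. With the filter on low counts, heat shock genes had 1 higher and 1 lower of 4 (median -0.08), hsp-16.2 (0.15) did not pass, and ER stress genes passed with 6 higher and 0 lower of 8 (median 0.81, adjusted permutation p = 0.00374).

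Immune regulators went both ways in H4K5ac, and the effectors were mostly below the typical listed gene, with medians that turned above 0 when scaled to the lowest 5% of genes. Of 16 listed p38 MAPK and immune regulators, 7 were higher and 3 lower (median 0.13, adjusted permutation p = 0.491). The bZIP factor gene cebp-1 (1.33 ± 0.13), the hypoxia factor gene hif-1 (1.06 ± 0.10), the nuclear receptor gene nhr-49 (0.89 ± 0.11) and hlh-30 (0.25 ± 0.08), the TFEB homologue of autophagy and host defence, were higher. The p38 kinase gene pmk-1 was lower (-0.37 ± 0.12, adjusted p = 0.0142, edgeR, 0.12 when scaled to the lowest 5%), while tir-1 (-0.14 ± 0.10) and sek-1 (0.07 ± 0.08), which act upstream of it, did not pass. Pathogen response effectors had 1 higher and 5 lower of 6 (median -0.34, 0.15 when scaled to the lowest 5%, adjusted permutation p = 0.104). The gene spp-1 (0.43 ± 0.14) was higher and clec-85 (-0.33 ± 0.09), cpt-4 (-0.36 ± 0.09) and clec-67 (-0.44 ± 0.11) were lower. C-type lectins had 2 higher, clec-87 (0.40 ± 0.08) and clec-126 (0.41 ± 0.15), and 9 lower of 13 (median -0.33, 0.17 when scaled to the lowest 5%, adjusted permutation p = 0.0505). The gene clec-63 (0.03 ± 0.12) did not pass. Lysozymes and saposin-like proteins had 1 higher and 5 lower of 8 (median -0.24, 0.25 in the other scaling, adjusted permutation p = 0.25). The gene spp-17 (0.06 ± 0.13) did not pass and spp-8 (-0.38 ± 0.08) and spp-10 (-0.21 ± 0.08) were lower. Detoxification genes (UDP-glucuronosyltransferases, glutathione transferases and cytochrome P450s) had 2 higher and 11 lower of 23, or 1 and 11 adjusted over the list alone (median -0.22, 0.28 in the other scaling, adjusted permutation p = 0.125). The genes gst-36 (0.12 ± 0.09), gst-42 (-0.04 ± 0.09), cyp-33C4 (0.05 ± 0.08) and cyp-32B1 (-0.08 ± 0.15) did not pass. Both listed pals genes, pals-18 (-0.46 ± 0.09, 0.04 in the other scaling) and pals-1 (-0.0031 ± 0.14, not passing), belong to a family induced by intracellular pathogens, and the list's median was -0.23. The effector genes irg-1 and lys-7 were in neither mark's list. The rank test of the C-type lectins passed without IP 2, input 2 or input 3 (adjusted permutation p = 0.0364, 0.0255 and 0.0368). Immune regulators had 5 lower without input 1, and lysozymes and saposin-like proteins 3 lower without input 3 and 2 higher without input 1. Detoxification genes had 1 higher without IP 2, IP 3, input 2 or input 3. The median of the pals genes was -0.14 without input 1. In this group 1 left-out library ended the call of hlh-30 (input 2 or 3, 0.20 to 0.27), spp-1 (IP 1 or 2, 0.28 to 0.62), clec-126 (IP 1 or 2 or input 2 or 3, 0.25 to 0.59) and spp-10 (IP 1 or 3 or input 1, 2 or 3, -0.24 to -0.19). Conversely, omission brought past the threshold spp-17 (input 1, -0.05 to 0.24) and tir-1 (input 1, -0.23 to -0.09). With the filter on low counts, immune regulators had 4 higher and 2 lower of 12 (median 0.04), lysozymes and saposin-like proteins 0 and 2 of 4 (-0.16), effectors 0 and 3 of 4, C-type lectins 1 and 8 of 11 (adjusted permutation p = 0.0357) and detoxification genes 1 and 9 of 15. The only pals gene left, pals-18, lay at -0.55. The genes hlh-30 (0.16), spp-1 (0.34) and clec-126 (0.32) did not pass with the filter, nor did spp-1 (0.44) and clec-126 (0.41) with DESeq2, where the C-type lectin list passed (adjusted permutation p = 0.0492).

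Among insulin signalling genes and acetyltransferase and deacetylase genes, more were higher than lower in H4K5ac, while the lists as a whole did not pass their rank tests. Of 10 insulin signalling and oxidative stress genes 8 were higher and 0 lower, among them the phosphatase gene daf-18 (0.85 ± 0.10) and the kinase genes akt-1 (0.85 ± 0.09), akt-2 (0.30 ± 0.09) and pdk-1 (0.22 ± 0.08), with a median of 0.31 (adjusted permutation p = 0.25). Histone acetyltransferase and deacetylase genes, with their cofactors, had 8 higher and 2 lower of 15, or 9 and 2 adjusted over the list alone (median 0.28, adjusted permutation p = 0.25). The acetyltransferase cofactor gene trr-1 (0.62 ± 0.10), the Mi-2 remodeller gene let-418 (0.52 ± 0.09), the ATP citrate lyase gene acly-1 (0.60 ± 0.09) and the ATPase gene ssl-1 (0.65 ± 0.09) were higher, and mys-1, the MYST acetyltransferase gene, did not pass (-0.17 ± 0.09). Core histone genes had 3 higher and 4 lower of 9 (median -0.17, 0.33 in the other scaling, adjusted permutation p = 0.46). The gene his-71 (0.38 ± 0.10) was higher, his-6 (0.0046 ± 0.09) did not pass and his-38 (-0.32 ± 0.09) and his-29 (-0.44 ± 0.10) were lower. Insulin signalling and oxidative stress genes had 5 higher without IP 3, input 2 or input 3. Acetyltransferase and deacetylase genes had 0 lower without input 2 or input 3 and 1 without IP 3. The core histone median was -0.27 without IP 1 and -0.10 without IP 3. Calls lost without 1 library were those of akt-2 (IP 3, 0.20 to 0.34) and pdk-1 (IP 1 or 3 or input 2 or 3, 0.16 to 0.26). Calls gained that way were those of mys-1 (input 1, -0.23 to -0.13). With replicate numbers as a block, mys-1 (-0.18) passed. Under the filter on low counts, 5 of 8 insulin signalling and oxidative stress genes were higher, pdk-1 (0.14) did not pass, acetyltransferase and deacetylase genes had 1 lower of 12, and core histone genes had 1 higher and 2 lower of 4. Without IP 1, his-71 was at 0.25.

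Collagen genes lay below the typical listed gene in H4K5ac, with a median that turned above 0 when scaled to the lowest 5% of genes, and germline markers lay around it. Collagens had 4 higher and 34 lower of 62 (median -0.29, 0.21 when scaled to the lowest 5%, adjusted permutation p = 0.00132). The genes col-111 (0.77 ± 0.11) and col-41 (0.31 ± 0.12) were higher and col-103 (0.30 ± 0.14) and col-52 (-0.15 ± 0.11) did not pass. Muscle markers had 1 higher and 10 lower of 16, or 1 and 12 adjusted over the list alone (median -0.27, 0.22 when scaled to the lowest 5%, adjusted permutation p = 0.0756). The myosin light chain gene mlc-3 was higher (0.36 ± 0.11), the tropomyosin gene lev-11 did not pass (0.0006 ± 0.08), and the myosin heavy chain gene unc-54 (-0.27 ± 0.08) and the obscurin gene unc-89 (-0.35 ± 0.08) were lower, at 0.23 and 0.15 when scaled to the lowest 5%. Intestine markers had 3 lower of 5, the protease genes asp-1 (-0.29 ± 0.10) and cpr-6 (-0.40 ± 0.08) among them, while erm-1 (-0.11 ± 0.11) and act-5 (-0.14 ± 0.09) did not pass (median -0.29, 0.21 in the other scaling, adjusted permutation p = 0.265). Germline markers had 4 higher, the RNA-granule gene car-1 (1.00 ± 0.10), the meiotic endonuclease gene spo-11 (0.74 ± 0.08), cbd-1 (0.40 ± 0.09) and the methyltransferase gene mes-4 (0.31 ± 0.08), and 8 lower of 25 (median -0.09, 0.41 in the other scaling, adjusted permutation p = 0.489). Neuron markers had 2 higher, the synaptobrevin gene snb-1 (1.14 ± 0.09) and the kinesin gene unc-104 (0.24 ± 0.09), and 5 lower of 11 (median -0.17, 0.33 in the other scaling, adjusted permutation p = 0.404). The genes unc-119 (0.07 ± 0.08) and egl-21 (0.09 ± 0.08) did not pass. Of 7 hypodermis and seam markers, 1 was higher, the spectraplakin gene vab-10 (0.47 ± 0.11), and 1 lower, with nhr-23 (0.16 ± 0.08), wrt-10 (-0.07 ± 0.10) and dpy-7 (0.20 ± 0.10) not passing (median -0.07, 0.43 in the other scaling, adjusted permutation p = 0.737). Without 1 library the threshold was no longer passed by col-41 (IP 1, 2 or 3 or input 2 or 3, 0.18 to 0.44), asp-1 (IP 2 or 3 or input 1, -0.39 to -0.21), mlc-3 (IP 1 or 2 or input 3, 0.27 to 0.47), unc-54 (input 2, -0.31 to -0.24) and unc-104 (IP 1 or 3 or input 1 or 2, 0.18 to 0.28). Newly past the threshold on such omission came col-103 (input 1, 0.12 to 0.46), erm-1 (input 1, -0.24 to -0.01) and dpy-7 (input 1, 0.09 to 0.26). The muscle list passed its rank test without IP 1, input 2 or input 3 (adjusted permutation p = 0.0037, 0.0379 and 0.0368). Collagens had 7 higher without input 1. The germline median was -0.16 without IP 1, -0.15 without input 3 and -0.05 without input 1. The neuron median was -0.28 without input 1 and -0.10 without input 2. The hypodermis median was 0.0028 without IP 1 and -0.18 without IP 2, where 2 were lower. It was -0.04 without input 1, where 2 were higher, and -0.04 without input 2. With replicate numbers as a block, collagens had 8 higher and 40 lower and hypodermis and seam markers 3 and 2, 2 muscle markers were higher, and col-103 (0.30), nhr-23 (0.16) and dpy-7 (0.20) passed. With the filter on low counts, collagens had 2 higher and 15 lower of 33, neuron markers 1 higher of 9, and the medians were -0.44 for muscle markers (adjusted permutation p = 0.0218), -0.17 for germline markers and -0.05 for hypodermis and seam markers. The genes col-41 (0.22) and unc-104 (0.15) then did not pass, and act-5 (-0.22) did. With DESeq2, 2 muscle and 2 hypodermis and seam markers were higher, and col-103 (0.31) and nhr-23 (0.16) passed.

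Nuclear receptors and F-box, BATH and MATH genes were also below the typical listed gene in H4K5ac, with medians that turned above 0 when scaled to the lowest 5% of genes. Nuclear hormone receptors had 11 higher and 33 lower of 78 (median -0.19, 0.31 when scaled to the lowest 5%, adjusted permutation p = 0.0195). The genes nhr-61 (0.63 ± 0.10), nhr-32 (0.54 ± 0.10) and nhr-71 (0.42 ± 0.08) were among the higher ones. F-box, BATH and MATH genes, which encode substrate adaptors of ubiquitin ligases, had 5 higher and 21 lower of 32, or 5 and 23 adjusted over the list alone (median -0.26, 0.23 when scaled to the lowest 5%, adjusted permutation p = 0.0214). The genes bath-36, bath-40 (1.01 ± 0.10), bath-44 (0.83 ± 0.09) and fbxb-85 (0.20 ± 0.08) were among the higher ones. Of 9 listed chemoreceptor genes 2 were higher and 6 lower, or 3 and 6 adjusted over the list alone (median -0.25, 0.25 in the other scaling, adjusted permutation p = 0.252). The higher ones were srbc-58 (1.41 ± 0.11) and stl-1 (0.50 ± 0.10), which the name pattern took in although it encodes a stomatin-like protein and no chemoreceptor, while srh-2 (0.29 ± 0.13) did not pass and srw-85 was lower (-0.25 ± 0.10). In the other 19 of the 24 lists with listed members, the count adjusted over the list alone was the same as that over all genes. The rank test of the nuclear hormone receptors did not pass without IP 1, input 2 or input 3 (adjusted permutation p = 0.0713, 0.06 and 0.0588). Chemoreceptor genes had 3 lower without IP 3. Leaving out 1 library ended the call of srw-85 (IP 2 or 3 or input 1, 2 or 3, -0.34 to -0.17) and fbxb-85 (IP 1, 2 or 3 or input 1, 2 or 3, 0.13 to 0.22). Gained calls were those of srh-2 (IP 2 or input 2 or 3, 0.16 to 0.38). With replicate numbers as a block, 18 nuclear hormone receptors were higher and 40 lower, and srh-2 (0.28) passed. Under the filter on low counts, chemoreceptor genes had 2 higher and 3 lower of 6 (median -0.07), F-box, BATH and MATH genes had 12 lower of 18, and fbxb-85 (0.11) did not pass. With DESeq2, srh-2 (0.29) passed.

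Being listed at all also differed between gene groups. In both marks it depends also on which gene a broad region was taken to, so an unlisted gene need not lack the mark. Of the 2161 genes listed for H4K5ac alone, 1400 had a region overlapping an H4K8ac region, as did 1049 of 1628 the other way. Against all protein-coding genes, muscle markers were over-represented among H4K5ac genes (16 of 24, odds ratio 8.09, 95% interval 3.26 to 21.8, adjusted p = 4.12e-06, two-sided Fisher's exact test over genes). So were germline markers (25 of 46, odds ratio 4.82), ER stress genes (11 of 22, 4.04), immune regulators (16 of 36, 3.23), autophagy genes (15 of 35, 3.03), acetyltransferase and deacetylase genes (15 of 39, 2.52), collagens (62 of 174, 2.25) and nuclear hormone receptors (78 of 269, 1.66). Under-represented were chemoreceptors (9 of 1309, odds ratio 0.0257), C-type lectins (13 of 239, 0.229), F-box, BATH and MATH genes (32 of 394, 0.351), detoxification genes (23 of 185, 0.570), pals genes (2 of 38, 0.223) and major sperm proteins (0 of 31, 0). The other 11 of the 25 lists did not pass, at 6 of 56 effectors, 8 of 46 lysozymes and saposin-like genes, 4 of 22 mitochondrial stress, 5 of 21 heat shock, 10 of 33 insulin signalling, 9 of 72 histone, 9 of 78 ribosomal protein, 9 of 25 translation and cytoskeleton, 5 of 27 intestine, 11 of 32 neuron and 7 of 25 hypodermis genes. Among genes with a ratio above the list median, muscle markers (4 of 24, odds ratio 1.68, adjusted p = 0.424), germline markers (2.05, 0.117), nuclear hormone receptors (1.06, 0.771) and collagens (0.733, 0.424) no longer passed, nor did pals genes (0.3) and major sperm proteins (0.137). Insulin signalling (odds ratio 3.16, adjusted p = 0.0155) and translation and cytoskeleton genes (4.74, 0.00256) then passed. With promoter regions only, ER stress genes (2.51, 0.119), acetyltransferase and deacetylase genes (1.22, 0.688), detoxification genes (0.63, 0.152), pals genes (0.371, 0.312) and major sperm proteins (0, 0.0631) did not pass, and translation and cytoskeleton genes did (3.77, 0.00951). Against only the genes listed for either mark, 0 lists were over-represented and 3 were under-represented, the C-type lectins, the F-box, BATH and MATH genes and the pathogen response effectors.

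**Figure D1:**
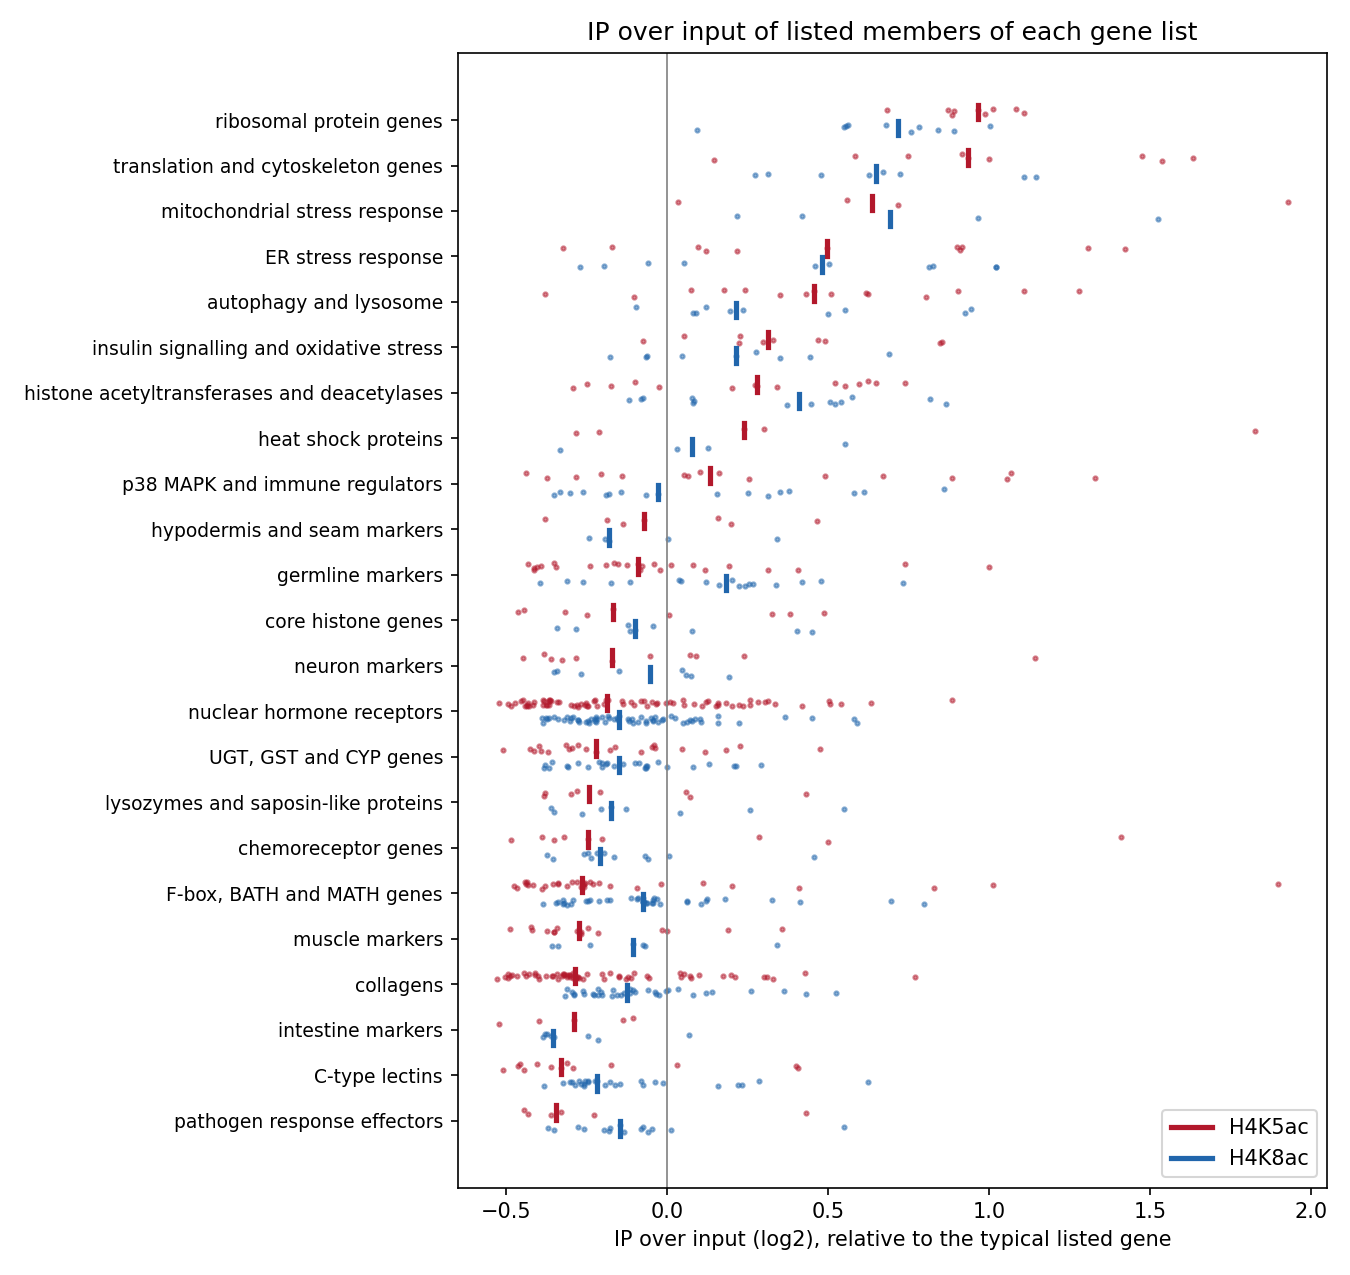
Log2 IP over input of each listed member (points) of the gene lists with at least 4 listed members in both marks, with the median of each list as a bar, for H4K5ac in red and H4K8ac in blue. The x axis is relative to the typical listed gene, ribosomal protein genes lie highest with medians of 0.97 and 0.72, and list medians below 0 turn above 0 when libraries are scaled to the lowest 5% of genes.

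H4K8ac, IP against input. The genes R107.5, hsp-60, mstr-1, F16A11.9 and M04B2.10 were among the 10 largest ratios in H4K8ac as in H4K5ac. R107.5 again had the largest ratio (chromosome III, 9043201 to 9065199), with 809 ± 90.7 CPM in the IP and 264 ± 20.0 CPM in the input (SD, n = 3 each), a log2 ratio of 1.62 ± 0.14 (SE, adjusted p = 1.31e-07, edgeR), followed by hsp-60 (1.52 ± 0.12, chromosome III, 1615201 to 1623599, promoter). The proteasome subunit gene rpn-3 stood at 1.39 ± 0.12 (chromosome III, 8442601 to 8453399, promoter), and the protein-coding genes mstr-1 (1.45 ± 0.11), F53C11.5 (1.38 ± 0.12) and W03F9.1 (1.30 ± 0.09) and the non-coding genes Y75B12B.16 (1.46 ± 0.09), F16A11.9 (1.42 ± 0.11), M04B2.10 (1.38 ± 0.09) and R03E9.10 (1.34 ± 0.12) completed the 10 largest ratios. The region of Y75B12B.16 (chromosome V, 15181401 to 15194199) overlaps that of bath-36 in H4K5ac. Among the 10 highest IP levels stood also btbd-10 (1.02 ± 0.12), pdtf-1 (1.04 ± 0.11) and H37A05.6 (0.93 ± 0.11).

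Of 4876 genes tested, 1720 were higher in IP than in input and 1776 were lower, whereas scaling to the lowest 5% of genes, which moved every ratio up by 0.37, gave 3772 higher and 0 lower (edgeR, and 0 lower at an unadjusted p under 0.05). The 10 lowest genes lay between -0.40 and -0.39. They were spe-11 (-0.39 ± 0.06), which encodes a sperm-supplied protein needed by the embryo, the nuclear receptor gene nhr-46 (-0.39 ± 0.06), F10D11.4 (-0.39 ± 0.06), F35E12.6 (-0.39 ± 0.06), C18E9.7 (-0.39 ± 0.06) and the non-coding genes F11D5.22 (-0.40 ± 0.06), F11A6.11 (-0.39 ± 0.06), F48B9.12 (-0.39 ± 0.06), H09G03.3 (-0.39 ± 0.06) and C16B8.9 (-0.39 ± 0.07). For spe-11, levels were 106 ± 4.69 CPM in the IP and 139 ± 1.88 CPM in the input (SD, n = 3 each, adjusted p = 1.77e-05, edgeR).

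Ribosomal protein, translation and cytoskeleton, ER stress, and acetyltransferase and deacetylase genes lay above the typical listed gene in H4K8ac, and for every list in H4K8ac the count adjusted over the list alone was the same as that over all genes. Ribosomal protein genes had 10 of 78 listed, 9 higher and 0 lower (median 0.72, adjusted permutation p = 4.2e-04). The genes rps-18 (0.89 ± 0.09), rpl-14 (0.55 ± 0.07), rps-24 (0.84 ± 0.07) and rps-28 (0.78 ± 0.07) were among the higher ones. Of 8 listed translation and cytoskeleton genes 8 were higher (median 0.65, adjusted permutation p = 0.00392). The genes tba-1 (1.11 ± 0.09), iscu-1 (0.72 ± 0.09), act-4 (0.48 ± 0.06) and pmp-3 (0.31 ± 0.07) were among them. ER stress genes had 6 higher and 2 lower of 10 (median 0.48, adjusted permutation p = 0.0203), led by the BiP genes hsp-4 (0.82 ± 0.09) and hsp-3 (0.81 ± 0.08), pek-1 (0.50 ± 0.08) and pdi-3 (1.02 ± 0.07). The acetyltransferase and deacetylase list had 8 higher and 0 lower of 14 (median 0.41, adjusted permutation p = 0.0232). The genes let-418 (0.52 ± 0.08), the chromodomain gene mrg-1 (0.87 ± 0.08) and ssl-1 (0.54 ± 0.06) were higher and pcaf-1 (0.08 ± 0.06) and mys-1 (-0.08 ± 0.06) did not pass, and trr-1 was not in the H4K8ac list. All 4 listed mitochondrial stress genes were higher, namely hsp-60, atfs-1 (0.22 ± 0.07), dve-1 (0.42 ± 0.06) and the protease gene clpp-1 (0.97 ± 0.08), with a median of 0.69 and too few members for the rank test. Autophagy and lysosome genes had 6 higher and 0 lower of 10 (median 0.22, adjusted permutation p = 0.321). The Atg8 homologue lgg-1 (0.94 ± 0.09), epg-7 (0.50 ± 0.07), epg-9 (0.55 ± 0.08) and atg-3 (0.92 ± 0.07) were higher. Insulin signalling and oxidative stress genes had 5 higher and 1 lower of 9, with akt-1 (0.69 ± 0.10) above, akt-2 (0.05 ± 0.06) and pdk-1 (-0.06 ± 0.06) not passing and the receptor gene daf-2 lower (-0.18 ± 0.06, 0.19 when scaled to the lowest 5%), and a median of 0.21 (adjusted permutation p = 0.366). Of 4 listed heat shock genes hsb-1 (0.55 ± 0.08) and hsp-43 (0.13 ± 0.05) were higher, hsf-1 was lower (-0.33 ± 0.05, 0.03 in the other scaling) and hsp-16.2 (0.03 ± 0.07) did not pass (median 0.08). The acetyltransferase and deacetylase list did not pass without IP 2 (adjusted permutation p = 0.0537) and had 1 lower without IP 1 or IP 3. ER stress genes had 1 lower without input 3, and autophagy genes 1 lower without IP 1. The heat shock median was 0.12 without IP 1 and 0.05 without IP 3. In this group 1 left-out library ended the call of hsp-43 (IP 2 or input 1, 2 or 3, 0.10 to 0.14) and daf-2 (input 3, -0.21 to -0.14). With the filter on low counts, insulin signalling and oxidative stress genes had 3 higher and 1 lower of 7 (median 0.01) and heat shock genes 1 and 1 of 3 (-0.00033). Ribosomal protein genes had 5 higher of 5, mitochondrial stress genes 2 of 2, and 1 ER stress, 1 autophagy and 1 acetyltransferase or deacetylase gene were lower.

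Of the immune lists in H4K8ac, the C-type lectins passed the rank test, below the typical listed gene, with a median that turned above 0 when scaled to the lowest 5% of genes. Of 17 immune regulators 8 were higher, with nhr-49 (0.58 ± 0.09), cebp-1 (0.86 ± 0.09), hif-1 (0.61 ± 0.09) and hlh-30 (0.15 ± 0.06), and 7 were lower (median -0.03, 0.34 when scaled to the lowest 5%, adjusted permutation p = 0.824). The p38 cascade genes pmk-1 (-0.30 ± 0.07), tir-1 (-0.26 ± 0.06) and sek-1 (-0.14 ± 0.05) were lower, at 0.06, 0.10 and 0.22 when scaled to the lowest 5%. Pathogen response effectors had 1 higher, spp-1 (0.55 ± 0.08), and 8 lower of 15 (median -0.15, 0.22 in the other scaling, adjusted permutation p = 0.288). The genes clec-85 (-0.15 ± 0.05) and cpt-4 (-0.20 ± 0.05) were among the lower ones and clec-4 (-0.08 ± 0.06) did not pass. C-type lectins had 5 higher and 17 lower of 27 (median -0.22, 0.15 when scaled to the lowest 5%, adjusted permutation p = 0.00903). The genes clec-87 (0.62 ± 0.08), clec-142 (0.23 ± 0.06) and clec-62 (0.16 ± 0.05) were higher and clec-80 (-0.16 ± 0.08) did not pass. Lysozymes and saposin-like proteins had 2 higher and 5 lower of 9 (median -0.17, 0.19 in the other scaling, adjusted permutation p = 0.293). The gene spp-17 (0.26 ± 0.06) was higher and the lysozyme genes ilys-5 (-0.36 ± 0.05) and lys-6 (-0.21 ± 0.06) were lower. Detoxification genes had 4 higher and 15 lower of 28 (median -0.15, 0.21 in the other scaling, adjusted permutation p = 0.0982). The gene gst-36 (0.13 ± 0.06) was higher, gst-42 (-0.07 ± 0.05) did not pass and cyp-33C7 (-0.20 ± 0.06) and cyp-13A2 (-0.36 ± 0.06) were lower. Of 3 listed pals genes pals-18 (-0.19 ± 0.06) and pals-28 (-0.29 ± 0.06) were lower and pals-1 (0.11 ± 0.06) did not pass (median -0.19, 0.17 in the other scaling). The median of the immune regulators was 0.015 without IP 2 and 0.012 without input 3, and -0.05 without IP 3 or without input 1. Calls lost without 1 library were those of hlh-30 (IP 2 or input 1, 2 or 3, 0.14 to 0.20), clec-85 (input 3, -0.17 to -0.12), clec-62 (input 3, 0.12 to 0.19), gst-36 (IP 2 or input 2 or 3, 0.10 to 0.16), pals-18 (input 1, -0.24 to -0.15) and sek-1 (IP 2 or input 2 or 3, -0.18 to -0.10). Calls gained that way were those of clec-80 (IP 1, -0.21 to -0.12) and pals-1 (IP 3, 0.07 to 0.16). With the filter on low counts, immune regulators had 5 higher and 7 lower of 15 (median -0.10), effectors 5 lower of 9, lysozymes and saposin-like proteins 3 lower of 5, and detoxification genes 1 higher of 18. The genes hlh-30 (0.12) and gst-36 (0.10) then did not pass, and clec-80 (-0.19) did. The median of the immune regulators was -0.01 with DESeq2.

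Among tissue markers the intestine list stood lowest in H4K8ac, relative to the typical listed gene, though not below 0 when scaled to the lowest 5% of genes. It had 7 lower of 8 (median -0.36, 0.0091 when scaled to the lowest 5%, adjusted permutation p = 4.2e-04). The genes asp-1 (-0.21 ± 0.05), the GATA factor gene elt-7 (-0.35 ± 0.06) and cpr-6 (-0.38 ± 0.06) were lower and act-5 (0.07 ± 0.05) did not pass. Germline markers had 9 higher and 4 lower of 18 (median 0.18, adjusted permutation p = 0.288). Without H4K8ac IP replicate 1 the germline median was 0.071, with 6 higher and 5 lower, and without H4K8ac IP replicate 3 it was 0.28. The genes car-1 (0.73 ± 0.09), mes-4 (0.48 ± 0.08), the germ-granule helicase gene glh-2 (0.34 ± 0.09) and the meiotic axis gene him-3 (0.22 ± 0.09) were higher. Collagens had 5 higher and 15 lower of 36 (median -0.12, 0.24 in the other scaling, adjusted permutation p = 0.138). The genes col-119 (0.36 ± 0.06), col-103 (0.26 ± 0.05) and col-97 (0.14 ± 0.05) were higher and col-52 (-0.17 ± 0.08) did not pass. Muscle markers had 1 higher, mlc-3 (0.34 ± 0.06), and 3 lower of 7 (median -0.11, 0.26 in the other scaling, adjusted permutation p = 0.556). The gene lev-11 (-0.07 ± 0.05) did not pass and unc-89 (-0.34 ± 0.06) and the perlecan gene unc-52 (-0.24 ± 0.06) were lower. Neuron markers had 1 higher, unc-104 (0.19 ± 0.05), and 4 lower of 8 (median -0.05, 0.31 in the other scaling, adjusted permutation p = 0.739). The genes unc-119 (0.06 ± 0.05) and egl-21 (0.07 ± 0.05) did not pass and the GABA synthesis gene unc-25 (-0.34 ± 0.06) was lower. Hypodermis and seam markers had 1 higher, vab-10 (0.34 ± 0.05), and 3 lower of 5 (median -0.18, 0.18 in the other scaling, adjusted permutation p = 0.371). The genes elt-1 (-0.24 ± 0.06) and mlt-11 (-0.18 ± 0.06) were lower and dpy-7 (0.0011 ± 0.06) did not pass. Without IP 1 the medians were -0.07 for collagens, -0.02 for neuron markers and -0.11 for hypodermis and seam markers. Without 1 library the threshold was no longer passed by col-97 (IP 2 or input 1 or 3, 0.12 to 0.16), him-3 (IP 1 or 2 or input 2 or 3, 0.10 to 0.34) and mlt-11 (input 1, -0.22 to -0.11). Newly past the threshold on such omission came col-52 (IP 1 or 2, -0.21 to -0.13). Without IP 1, glh-2 was at 0.21. Under the filter on low counts, neuron markers had 1 higher and 2 lower of 5 (median 0.03), collagens 3 and 9 of 20, intestine markers 4 lower of 5 and germline markers 1 lower of 14. The genes col-97 (0.11) and him-3 (0.19) did not pass with it, nor did him-3 (0.24) with DESeq2, and col-52 (-0.20) passed.

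Nuclear hormone receptors lay below the typical listed gene in H4K8ac as well, with 7 higher, nhr-14 (0.59 ± 0.07), nhr-61 (0.45 ± 0.06) and nhr-21 (0.22 ± 0.07) among them, and 32 lower of 63 (median -0.15, 0.22 when scaled to the lowest 5%, adjusted permutation p = 0.0137). F-box, BATH and MATH genes had 5 higher, with bath-44 (0.69 ± 0.09) and bath-40 (0.80 ± 0.08), and 15 lower of 41 (median -0.07, 0.29 in the other scaling, adjusted permutation p = 0.371). The genes fbxa-167 (-0.07 ± 0.06) and fbxc-45 (0.12 ± 0.06) did not pass. Core histone genes had 2 higher and 2 lower of 9 (median -0.10, 0.27 in the other scaling, adjusted permutation p = 0.556). The gene his-63 (0.45 ± 0.08) was higher, his-71 (0.08 ± 0.06) did not pass and his-38 (-0.34 ± 0.06) and his-29 (-0.28 ± 0.05) were lower. Chemoreceptor genes had 1 higher, again stl-1 (0.46 ± 0.08), and 8 lower of 12 (median -0.21, 0.16 in the other scaling, adjusted permutation p = 0.0982). The genes srv-1 (-0.24 ± 0.05), srh-2 (-0.16 ± 0.05) and srx-14 (-0.25 ± 0.05) were lower. Of 3 listed major sperm protein genes msp-32 (-0.20 ± 0.06) and msp-152 (-0.23 ± 0.07) were lower and msp-31 (-0.10 ± 0.05) did not pass (median -0.20, 0.17 in the other scaling). The nuclear hormone receptors did not pass without IP 2 (adjusted permutation p = 0.0657) and had 4 higher without input 1 or input 2. F-box, BATH and MATH genes had 9 higher without IP 3. Core histone genes had 4 lower without IP 2 and a median of -0.04 without IP 1. With a filter on low counts the nuclear hormone receptor list passed in neither mark (adjusted permutation p = 0.0598 and 0.151). Leaving out 1 library ended the call of srh-2 (IP 2, -0.20 to -0.12) and nhr-21 (input 1 or 2, 0.19 to 0.28). Gained calls were those of fbxc-45 (IP 3, 0.09 to 0.18). With that filter, F-box, BATH and MATH genes had a median of -0.12, core histone genes had 1 higher of 5, and msp-31 (-0.13) passed. With DESeq2, fbxc-45 (0.14) passed.

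Immune regulators (17 of 36, odds ratio 4.0, 95% interval 1.95 to 8.13, adjusted p = 5.86e-04, two-sided Fisher's exact test over genes), ER stress genes (10 of 22, 3.72), germline markers (18 of 46, 2.87) and acetyltransferase and deacetylase genes (14 of 39, 2.5) were over-represented among H4K8ac genes. Chemoreceptors (12 of 1309, odds ratio 0.0380), F-box, BATH and MATH genes (41 of 394, 0.512) and C-type lectins (27 of 239, 0.564) were under-represented, and the other 18 of the 25 lists did not pass. With promoter regions only, ER stress genes (odds ratio 2.25, adjusted p = 0.352), acetyltransferase and deacetylase genes (1.98, 0.284) and C-type lectins (0.735, 0.425) did not pass and nuclear hormone receptors did (1.63, 0.019). Among genes with a ratio above the list median, autophagy (3.26, 0.0136), translation and cytoskeleton (4.43, 0.00633) and detoxification genes (0.312, 0.00633) passed too. Against only the genes listed for either mark, 0 lists were over-represented and 1, the collagens, was under-represented.

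H4K5ac against H4K8ac. Both marks lay over largely shared regions and ranked shared genes alike. Of the H4K5ac regions, 5091 (83.4%, Wilson interval 82.5 to 84.4) overlapped an H4K8ac region by at least 1 base, as did 4680 (86.5%, 85.6 to 87.4) of the H4K8ac regions, with 31.6 Mb in common. The protein-coding genes listed for H4K5ac (3973) and H4K8ac (3665) shared 2521, where independent lists of these sizes would share 728.7 (odds ratio 22.6, 95% interval 20.6 to 24.7, Fisher's exact test over genes). Among 3245 genes with values in both marks, 987 were higher than input in both, where independent calls would give 436.1, 599 were lower in both (246.2), and 8 and 5 were called in opposite directions. Across these genes, which are not independent replicates, the ratios of the marks had a Pearson correlation of 0.898 and a Spearman correlation of 0.854. Genes listed for H4K5ac alone numbered 2161, of which 761 had no overlapping H4K8ac region, and 1628 were listed for H4K8ac alone, of which 579 had no overlapping H4K5ac region. A further 3 listed names, hrp-1, rad-26 and a name altered to a date, stood in both lists but were not matched to the same gene in both and were not compared.

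Between the IP libraries, 752 of 3245 genes differed (edgeR, Benjamini-Hochberg), 400 higher in H4K5ac and 352 higher in H4K8ac. The phosphodiesterase gene pde-6 was higher in H4K5ac by 0.82 ± 0.14 on the log2 scale (chromosome I, 872801 to 876799), with 922 ± 198 CPM for H4K5ac and 524 ± 33.9 CPM for H4K8ac (SD, n = 3 each, adjusted p = 6.53e-06, edgeR), followed by the RNA-binding gene sup-26 (0.71 ± 0.13), Y59A8B.24 (0.70 ± 0.09), F07A11.15 (0.70 ± 0.09), the ATP synthase subunit gene asb-2 (0.69 ± 0.09), ile-2 (0.68 ± 0.09), T04C10.7 (0.67 ± 0.10), fnip-2 (0.66 ± 0.12), tub-2 (0.66 ± 0.09) and the proteasome gene pbs-1 (0.65 ± 0.15). C46A5.1 led the genes higher in H4K8ac at -0.57 ± 0.10 (chromosome IV, 7763601 to 7765399), with 217 ± 25.9 CPM for H4K5ac and 321 ± 48.3 CPM for H4K8ac (adjusted p = 9.11e-06, edgeR). Next were him-8 (-0.53 ± 0.09), which encodes the zinc-finger protein of X chromosome pairing in meiosis, mans-4 (-0.53 ± 0.09), duo-1 (-0.52 ± 0.09), the pantothenate kinase gene pnk-1 (-0.51 ± 0.09), ZC513.14 (-0.51 ± 0.09), the sex-determination gene tra-2 (-0.49 ± 0.09), C40H1.7 (-0.49 ± 0.09), mcat-1 (-0.48 ± 0.09) and metl-13 (-0.48 ± 0.09). After removal of a trend on H4K8ac enrichment pbs-1 did not pass (0.30, adjusted p = 0.168, edgeR), and pde-6, F07A11.15 and T04C10.7, still past the threshold, were at 0.51, 0.35 and 0.37. Relative to each mark's own input 11 of these 20 genes did not pass, among them pde-6 (0.46), fnip-2 (0.44), pnk-1 (-0.31), ZC513.14 (-0.29) and tra-2 (-0.23). The count rested on single libraries, at 229 and 475 without H4K8ac IP replicates 2 and 3 and 494 without H4K5ac IP replicate 1. It was 194 and 327 without replicate 2 or 3 of both marks. Taken relative to each mark's own input it was 129, or 233 without H4K5ac input replicate 1, and each mark had its own inputs, so mark and chromatin preparation cannot be told apart.

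Germline genes carried relatively more H4K8ac, while translation and cytoskeleton genes carried relatively more H4K5ac. Of 14 germline markers measured in both marks, 8 were higher in H4K8ac and 0 in H4K5ac, with a median log2 difference of -0.26 (permutation p = 4e-05, adjusted p = 7.6e-04 over the 19 lists with at least 5 shared members). Those higher in H4K8ac included the egg-surface gene egg-2 (-0.45 ± 0.09), the P-granule gene pgl-2 (-0.44 ± 0.09), the yolk receptor gene rme-2 (-0.40 ± 0.09) and the translational repressor gene fbf-1 (-0.40 ± 0.09). The gene car-1 went the other way (0.28 ± 0.12) and did not pass over all genes. Adjusted over the list alone 12 differed, car-1 among them. With the replicate block 8 germline markers were higher in H4K8ac and 1 in H4K5ac. Of 8 translation and cytoskeleton genes 5 were higher in H4K5ac (5 adjusted over the list alone), with a median of 0.29 (permutation p = 6.4e-04, adjusted p = 0.00608), among them act-4 (0.61 ± 0.11), tba-1 (0.42 ± 0.13) and act-2 (0.34 ± 0.09), but after removal of a trend on H4K8ac enrichment the median was 0.05 (permutation p = 0.351). F-box, BATH and MATH genes had 8 of 20 higher in H4K8ac (8 adjusted over the list alone), bath-4 (-0.44 ± 0.10) and fbxa-215 (-0.36 ± 0.10) among them (median -0.17, adjusted permutation p = 0.0158), though not when genes were taken from promoter regions only (permutation p = 0.14). The other 16 lists with a rank test did not pass. Adjusted over the list alone, the acetyltransferase and deacetylase list had 5 genes that differed in place of 3, the ribosomal protein list 4 in place of 1 and the nuclear hormone receptors 4 in place of 10. Lists that did not pass included 9 autophagy genes (4 higher in H4K5ac, median 0.19, adjusted permutation p = 0.0891), 28 collagens (6 higher in H4K5ac, 0.08, 0.204), 13 immune regulators (3 higher in H4K5ac and 1 in H4K8ac, -0.05, 0.862) and 53 nuclear hormone receptors (5 and 5, -0.05, 0.507). Single libraries moved these counts: the germline count was 4 without H4K8ac IP replicate 1 or 2 or H4K5ac IP replicate 3. Without H4K8ac IP replicate 2 the translation and cytoskeleton and the F-box, BATH and MATH counts were 1 each. Without H4K8ac IP replicate 3 or H4K5ac IP replicate 1 the former was 3, and without H4K8ac IP replicate 1 the latter was 5. The highest permutation p of the list median over the 6 omissions was 0.00868, 0.0041 and 0.00556 for these lists, unadjusted. Members named here outside the rule were chosen after their values were seen.

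**Figure D2:**
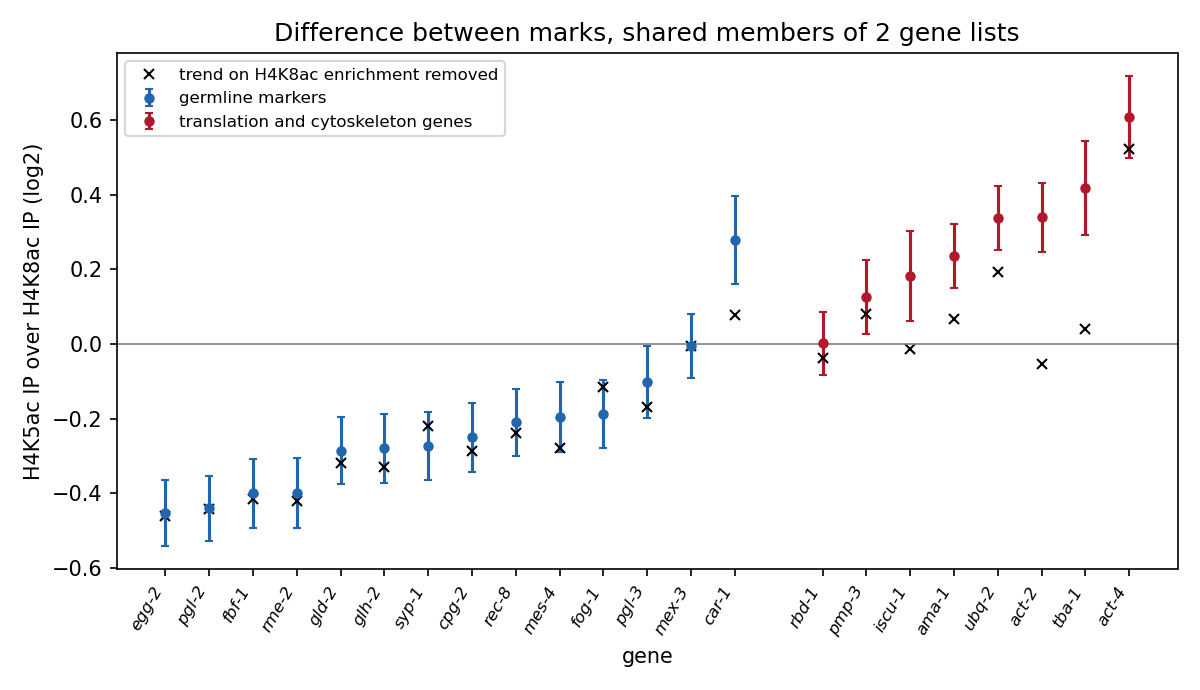
Log2 difference between the H4K5ac IP and the H4K8ac IP for each member of the germline list (blue) and of the translation and cytoskeleton list (red) measured in both marks, as estimate ± SE from 3 libraries a mark, with black crosses after removal of a trend on H4K8ac enrichment. The median of the germline list is -0.26 before and -0.28 after that removal, and that of the translation and cytoskeleton list 0.29 and 0.05.

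Chromosome X was examined after a contrast between the marks had been noticed there. Of the X-linked genes that differed, 143 were higher in H4K5ac and 20 in H4K8ac, against 257 and 332 on the autosomes, and asb-2, ile-2 and T04C10.7 are X-linked. These genes come from the same 6 libraries and include neighbours, so they are not independent. The median log2 difference was 0.08 over 634 X-linked genes and -0.03 over 2611 autosomal genes. Relative to each mark's input the counts were 38 and 0 on X against 30 and 61 on the autosomes, and without H4K8ac IP replicate 2 they were 49 and 1 against 101 and 78. Per library, the median X-linked gene less the median autosomal gene was -0.018 ± 0.031 (log2, SD, n = 3) in the H4K5ac IP and -0.118 ± 0.065 in the H4K8ac IP (exact permutation p = 0.1, two-sided, the smallest that 3 against 3 allow), and -0.025 ± 0.064 and 0.036 ± 0.0085 in the inputs (exact permutation p = 0.1). The nearest IP libraries were H4K5ac IP replicate 1 at -0.0489 and H4K8ac IP replicate 3 at -0.0498. Over all genes listed for each mark, which are different genes, the order was the opposite, at -0.149 ± 0.017 in the H4K5ac IP and -0.081 ± 0.053 in the H4K8ac IP (SD, n = 3). The inputs there lay at -0.059 ± 0.063 and 0.032 ± 0.013. IP less input was -0.090 for H4K5ac (exact permutation p = 0.2, unpaired) and -0.113 for H4K8ac (exact permutation p = 0.1, the smallest possible). Within the H4K5ac replicate numbers, taken as pairs after the data were seen, it was -0.033, -0.124 and -0.113 (exact sign-flip permutation p = 0.25, two-sided, the smallest that 3 pairs allow).

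**Figure D3:**
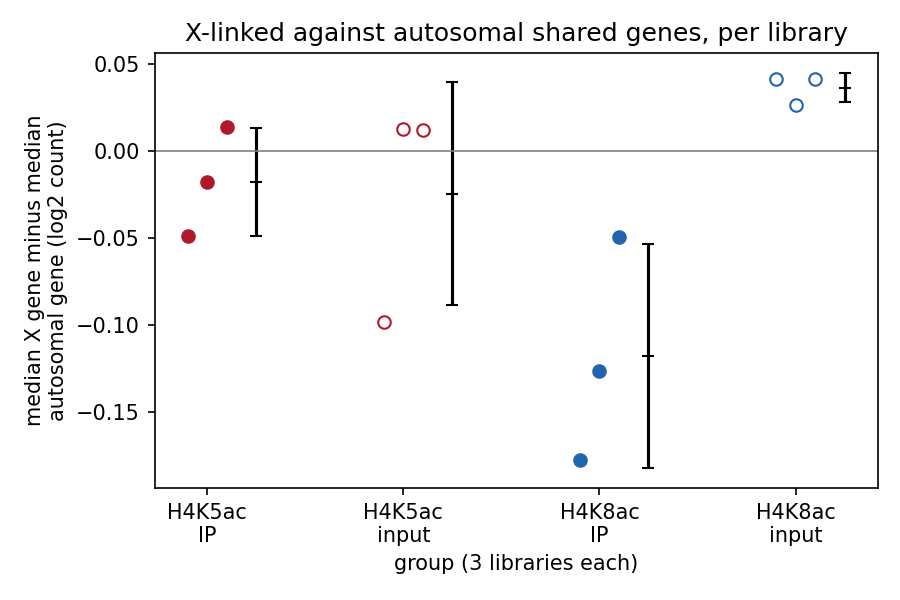
Median log2 count of X-linked genes less that of autosomal genes, over genes measured in both marks, in each of the 12 libraries (filled circles IP, open circles input, red H4K5ac, blue H4K8ac), with mean and SD per group in black. The H4K8ac IP libraries average -0.118 and the H4K5ac IP libraries -0.018, while H4K5ac input replicate 1 lies at -0.099.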

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

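The tests of this part were chosen after the data were seen, except the counts of genes in the real groups and the omission of single libraries. The gene lists and their rank test within each mark had been fixed beforehand, and its use between the marks had not. The IP over input ratio differed between the marks for 129 genes (interaction of mark and IP, edgeR with Benjamini-Hochberg adjustment, 3 libraries per group), 233 without H4K5ac input replicate 1. Of the genes named between the marks, the log2 interaction was 0.90 for Y59A8B.24 (adjusted p = 0.0041), 0.71 for asb-2, 0.67 for tub-2, 0.60 for ile-2 and 0.58 for sup-26, all relatively higher in H4K5ac. It was -0.59 for C46A5.1 (adjusted p = 0.0334), -0.53 for mans-4, -0.45 for duo-1 and -0.44 for mcat-1, all relatively higher in H4K8ac. The other 11 genes named there did not pass the interaction test.

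Input replicate 1 of H4K5ac stood apart. Its log2 deviation from inputs 2 and 3 had an SD of 0.226 across 5409 genes, against 0.0636 for the difference between inputs 2 and 3 and 0.062 for the same deviation of H4K8ac input replicate 1. Were IP material mixed into it, removing the profile of IP replicate 1 should leave little, yet the remaining SD was 3.01 times that between inputs 2 and 3, which argues against such mixing as the whole cause. A chromatin preparation shared with IP replicate 1 may account for it, since the deviations of both correlated at 0.60 across genes. Mixing would give such a correlation too, so it does not tell the explanations apart. The deviation of input 1 correlated at 0.53 with the profile of IP 1 and at 0.37 with that of IPs 2 and 3, each over inputs 2 and 3. Counts of input 1 correlated with region width at 0.15, against 0.02 and 0.03 for inputs 2 and 3 (Spearman). Mixing as a part of the cause stays open. No biological explanation was tested, because the labels name no difference between replicates.

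Shared germline markers carried relatively more H4K8ac, with a median log2 difference of -0.26, though more were listed for H4K5ac. This list, the translation and cytoskeleton list and the F-box, BATH and MATH list were followed because their tests had passed among 19. A wider range of enrichment in the H4K5ac IP is argued against, since the median was -0.28 after the trend on H4K8ac enrichment was removed. A difference between the inputs is argued against too, with a median of -0.38 relative to them. Dependence on a single library stays open, since the median was -0.19 without H4K8ac IP replicate 1, the smallest of the 6 omissions. Another share of germline nuclei in the worms used for each mark could give the same pattern, which was not tested, and a difference between the marks themselves cannot be separated from it, as mark and chromatin preparation go together.

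Translation and cytoskeleton genes carried relatively more H4K5ac, with a median log2 difference of 0.29. A wider range of enrichment in the H4K5ac IP may account for it, since the median was 0.0535 after the trend was removed. The inputs are argued against as the cause, with a median of 0.25 relative to them. A difference between the marks themselves was not tested apart from the preparations and stays open.

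For each count of genes, 3 libraries against 3 make 10 splits, so the share of splits with as large a count is never under 0.1. The real split gave 3456 genes for H4K5ac IP against input, 3496 for H4K8ac and 752 between marks, and the highest of the others gave 0 in each (edgeR). At an unadjusted p under 0.05 the highest of the others gave 298, 31 and 455. In each case 1 of the 10 splits, the real one, reached the real count. The splits took no account of replicate numbers.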

How the results depend on the processing

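Scaling to the lowest 5%, DESeq2 between marks, omitting a replicate number from IP and input, values relative to inputs and trend removal were chosen after the data were seen. The count of 3456 for H4K5ac ranged from 2213 to 4003 with libraries left out, the lowest without replicate 3 in both groups, and that of 3496 for H4K8ac from 2770 to 3662. DESeq2 and the filter on low counts kept both within 1.5 times. Between marks, 752 became 229 to 815 with 1 library left out. It was 832, 194 and 327 without replicates 1, 2 and 3 of both marks and 364 with promoter regions only (1738 tested). It was 129 relative to inputs (233 without H4K5ac input replicate 1), 504 with the trend removed and 985 with DESeq2. Same-numbered H4K8ac IP and input libraries did not deviate together (r = -0.12, -0.05 and 0.06), nor did all of those of the marks (0.17, 0.30 and 0.085), so they share only a number. With the replicate block 3455 genes passed in H4K8ac and 953 between marks.

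Of the named genes, 56 of 118 in H4K5ac, 57 of 122 in H4K8ac and 9 of 20 between marks kept direction and side of the threshold in every alternative run, and 84 and 102 within the marks did so in all but scaling to the lowest 5%. The replicate block gave the calls named in the report for H4K5ac, ended those of gst-36 and hsp-43 in H4K8ac, and changed no other call of a named gene. Of the 25 lists, the presence of 10 in H4K5ac and 13 in H4K8ac kept direction and side. Scaling to the lowest 5% raises every ratio by construction. It turned the sign of 15 called genes in H4K5ac, namely clec-85 (0.17), cpt-4 (0.14), clec-67 (0.0537), spp-8 (0.12), spp-10 (0.29), hsf-1 (0.22), his-38 (0.18), his-29 (0.0548), asp-1 (0.21), cpr-6 (0.10), unc-54 (0.23), unc-89 (0.15), srw-85 (0.25), pals-18 (0.0376) and pmk-1 (0.12). In H4K8ac it turned 27, namely clec-85 (0.22), cpt-4 (0.17), ilys-5 (0.0032), lys-6 (0.16), cyp-33C7 (0.16), cyp-13A2 (0.0089), hsf-1 (0.0336), daf-2 (0.19), his-38 (0.0218), his-29 (0.0822), asp-1 (0.15), elt-7 (0.0123), unc-89 (0.026), unc-52 (0.12), unc-25 (0.024), elt-1 (0.12), mlt-11 (0.18), srv-1 (0.13), srh-2 (0.20), srx-14 (0.12), msp-32 (0.17), msp-152 (0.14), pals-18 (0.17), pals-28 (0.0757), pmk-1 (0.0638), tir-1 (0.10) and sek-1 (0.22). It also turned called list medians, in H4K5ac those of collagens (0.21), nuclear hormone receptors (0.31) and F-box, BATH and MATH genes (0.23), and in H4K8ac those of C-type lectins (0.15), intestine markers (0.0091) and nuclear hormone receptors (0.22). The rank tests of the H4K5ac C-type lectins and autophagy genes passed with DESeq2 (adjusted permutation p = 0.0492 each). Those of the C-type lectins (0.0357), ER stress genes (0.00374) and muscle markers (0.0218) passed with the filter on low counts. The replicate block changed no rank test but that of the H4K5ac autophagy genes.

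Overlap with the other mark fell to 60.1% (H4K5ac) and 67.8% (H4K8ac) of regions when 50% of both had to overlap. It was 70.4% and 77.7% for promoter regions and 79.2% and 85% for genes with a ratio above the list median. With genes named in any file as background, 3 lists in H4K5ac and 1 in H4K8ac were past the threshold, and odds ratios turned for the H4K8ac C-type lectins (3.58), germline markers (0.647), chemoreceptors (1.59) and F-box, BATH and MATH genes (1.36). For genes above the median ratio that of the H4K5ac collagens turned (0.733). Apart from what the constructions show, the cause was not tested. Pseudocounts and median or quantile normalization were not run because the values are counts. A stricter threshold and another overlap for IP against input were not run, as both share regions, nor replicate rules for regions, as each mark has 1 list. Total depth is unknown. The 4% recovery of 1.2-fold changes in H4K5ac held for 200 changed genes, so it is no limit of the real fit.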

Other observations

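The description of region width, gene types, chromosomes and genes of a single mark below was chosen after the data were seen, and the tests in it were not planned. Small RNA genes are given by type relative to the typical listed gene. Differences between types were not tested, and scaling to the lowest 5% moves every ratio up by 0.50 in H4K5ac and 0.37 in H4K8ac. Transfer RNA genes had 8 higher and 39 lower of 80 in H4K5ac (median log2 ratio -0.24) and 11 higher and 40 lower of 75 in H4K8ac (-0.15). Genes of piRNAs, the small RNAs that guard the germline genome, had 19 higher and 52 lower of 127 (-0.21) and 19 higher and 55 lower of 99 (-0.19). MicroRNA genes had 16 higher and 8 lower of 33 (0.12) and 19 higher and 11 lower of 37 (0.22). Genes of snoRNAs, which guide modification of ribosomal RNA, had 21 higher and 25 lower of 64 (-0.03) and 27 higher and 11 lower of 55 (0.13). Chromosomes V and X had the lowest medians, at -0.10 and -0.11 in H4K5ac and -0.06 and -0.12 in H4K8ac. Wide regions carried the higher ratios: the median went from -0.33 in the narrowest 5th of H4K5ac genes to 0.42 in the widest, and from -0.22 to 0.34 in H4K8ac (Spearman correlation across genes 0.60 and 0.56).

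Genes listed for 1 mark with no overlapping region of the other were mostly not enriched beyond the typical listed gene. Of 761 such genes in H4K5ac and 579 in H4K8ac, 26 and 18 had a ratio past the threshold and above 0, and a region missing from a list need not lack the mark. In H4K5ac they included the RNA-binding protein genes rbm-39 (1.38 ± 0.13, log2 ± SE, n = 3) and rbm-12 (1.05 ± 0.11), the chaperonin gene cct-3 (1.19 ± 0.10), the intersectin gene itsn-1 (1.13 ± 0.13), npr-23 (0.81 ± 0.11), nape-2 (0.76 ± 0.11), pisy-1 (0.75 ± 0.09), vem-1 (0.72 ± 0.08), sop-3 (0.70 ± 0.09) and the transcription elongation kinase gene cdk-12 (0.64 ± 0.10). In H4K8ac they included usp-3 (0.85 ± 0.09), ZK1307.8 (0.71 ± 0.09), agef-1 (0.64 ± 0.07), E02D9.1 (0.48 ± 0.08), the DNA repair gene fcd-2 (0.44 ± 0.07), dhs-24 (0.40 ± 0.06), the cohesin gene smc-3 (0.39 ± 0.07), acdh-9 (0.36 ± 0.08), the piRNA gene 21ur-6602 (0.34 ± 0.06) and Y61A9LA.10 (0.34 ± 0.08). These genes fall outside the rule and were chosen after their values were seen.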
